A study of Mus musculus with 2 samples.

How the data were processed

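The series held long-read RNA sequencing of total RNA from heart tissue of female B6CASTF1/J mice at 14 days of age, in 2 libraries of 1 group. Per the labels, the libraries are biological replicates 1 and 2 of 1 experiment and spike-in RNA was added to both. The labels of replicate 2 name the animal differently in separate fields, so nothing clearly says which animals the libraries came from. The deposited tables give the count of reads per transcript model as whole numbers, with each model's gene, number of exons, length and class, and list models with at least 1 read. Per the text deposited with each library, the authors quantified filtered alignments on mm10 with GENCODE release M21, 1 library at a time. Per the file headers, the models were built and named by TALON, which assigns each read to an annotated transcript or to a class of unannotated model. The aligner, its settings, the filters and the versions of tools are not given in the sources used here. The classes are annotated, incomplete (part of an annotated intron chain), new combination of known splice sites, new splice site, antisense to a gene, intergenic, and genomic (reads with no match to a splicing pattern, within a gene).

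Replicate 1 held 896941 reads, of which 12223 were on ERCC spike-ins, and replicate 2 held 972159, of which 12825 were on spike-ins. Reads per gene were summed over all classes except genomic, spike-ins left out, and divided by the totals of such reads, 858071 and 926560, to give CPM. A count of 0 allows up to 3 reads, or 3.50 CPM in replicate 1 and 3.24 in replicate 2. The files name genes with Ensembl identifiers and symbols, and members of lists were found by symbol. Unannotated models carry identifiers that differ between the libraries, because each library was processed alone, so models were matched by chromosome, strand and intron chain. Reads of a gene can also be placed in another class, or on an overlapping gene, in a single library. For the genes named as differing, reads of any class on models overlapping the gene on its strand were therefore counted as well, which was chosen after the data had been seen. No genome sequence was used here. Coordinates are 1-based on mm10, from the deposited models or the GENCODE M21 annotation.

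The following choices were made before the data were examined. The genes were taken in 25 lists: sarcomere, excitation-contraction coupling and calcium handling, fatty acid uptake and oxidation, glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded proteins, cell cycle, cardiac transcription factors and coactivators, RNA-binding splicing regulators, imprinted and growth genes, markers of atrium, conduction system, fibroblasts, endothelium, smooth muscle and pericytes, epicardium, macrophages and leukocytes, erythroid cells, skeletal muscle, adipocytes, lung, liver, thymus and lymphocytes, and glia and neurons, and stress and immediate early genes. A member counted as detected with at least 3 reads in both libraries. For 16 pairs of genes, the share of the second gene in the pair's reads was set against 50% in each library with a two-sided exact binomial test. For 54 genes with known alternative splicing in striated muscle, the share of the leading form was taken among annotated forms and unannotated ones with at least 5 reads in each library, and compared between the libraries by a two-sided Fisher's exact test where each library had at least 20 such reads. In the same genes, inclusion of an internal exon was the percent of reads, on forms holding the flanking splice sites, that include it. Exons had to have at least 20 such reads in each library and a mean inclusion of 5 to 95%. Fisher's exact test was also applied to these exons, which was added after the data had been seen.

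Reads per gene were compared between the libraries with a two-sided exact binomial test given the totals, over genes with at least 10 reads in all, as there were no replicates within either library. The test compares these libraries, not conditions. Gene list shifts were the median log2 ratio of CPM + 1, replicate 2 over replicate 1, of members with a mean of at least 10 reads, with the percentile among 10000 random lists of the same size matched on mean expression in 10 bins; a list needed 3 such members. All p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. Intervals are at 95% and are exact Clopper-Pearson intervals, apart from those over resampled members of a list and that of the spike-in lengths. The interval of the spike-in lengths is an exact conditional one. The text names, by rule, the 4 highest members of each list, all pairs, the isoform genes with at least 50 usable reads in each library and a leading share under 90% (at most 20), plus Tnnt2, Ttn, Ldb3, Camk2d and Atp2a2. It also names the 15 exons nearest 50%, the 20 genes highest by mean CPM, the 10 unannotated forms with the most reads and the 5 with the highest share of their gene among genes with at least 50 reads in each library. Between the libraries it names the 10 genes with the largest log2 ratio in each direction among those past the threshold with at least 50 reads in all. Results for some items that these rules name are not reported here.

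The alternatives were totals scaled by TMM (edgeR 4.0.16) or by DESeq2 1.42.0 size factors, other read minimums and pseudocounts, annotated models alone, incomplete or genomic models counted, mitochondrial genes left out, the deeper library thinned, matching by the identifiers in the files, reads summed over both libraries, each library alone, and edgeR's exact test with an assumed coefficient of variation of 0.1 or 0.2. Counting genomic models in the gene results and subtracting the trend with transcript length, as the median log2 ratio in 20 bins of genes with at least 50 reads in all, were added after the data had been seen. The tests were run on simulated data with counting error only, with 9433 genes drawn from the real means and totals. When none was changed, 0 were called. The changed genes were picked among the 4883 with at least 50 reads in all. Of 100 genes changed 2-fold and 100 changed 4-fold, 61% and 92% were recovered in the right direction. Of the genes called there, 0.649% had not been changed. The real counts differed by more than counting error, so these rates may not hold for them. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3.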

Results

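Full-length transcripts of heart tissue from female B6CASTF1/J mice, an F1 hybrid strain, were measured at 14 days of age by long-read RNA sequencing. There was 1 group with 2 libraries, replicates 1 and 2, so no condition was compared, and the values describe the heart at this age and the difference between the libraries. Replicate 1 held 896941 reads and replicate 2 held 972159. A single read was worth 1.17 CPM, the read count scaled to the library's total, in replicate 1 and 1.08 in replicate 2, and a count of 0 allowed up to 3.50 and 3.24 CPM. The labels number the libraries as biological replicates but do not clearly name separate animals, and a description shared by both refers to females in the plural. Every p-value given therefore covers counting error only, as does every interval except those over resampled members of a list. Those cover the spread among the members, which are not independent replicates. The spread between the libraries may be technical.

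Genes of contraction and of mitochondrial energy supply gave the most reads. Myh6, the alpha myosin heavy chain of adult mouse heart (ENSMUSG00000040752.16; mm10 chromosome 14, 54941921 to 54966927), reached 31270.1 CPM in replicate 1 and 30799 in replicate 2. Slc25a4, which exchanges ADP and ATP across the inner mitochondrial membrane, followed at 18475 ± 2402 CPM (SD, n = 2), then Tpm1, a tropomyosin, at 14265 ± 633. For Slc25a4, 2525 reads in replicate 2 and 0 in replicate 1 were classed as genomic and left out. With these reads counted it stood at 19566 and 18835 CPM in replicates 1 and 2. Ckm, the muscle creatine kinase, stood at 10242 ± 546 CPM, Atp5b of the ATP synthase at 9920.5 ± 28.9 and Atp2a2, the calcium pump of the sarcoplasmic reticulum, at 8850.3 ± 115. Among the other genes of the highest 20 were Atp5a1, Hba-a1, Fabp3, Uqcrc1, Myl3, Cox4i1, Tnnc1, Aldoa, Actc1, Col3a1, Hadhb, Hbb-bs and Eno3, from 8020.2 CPM for Atp5a1 to 3997 for Eno3. Together the 20 genes took 17.4% ± 0.133 of the reads behind CPM, antisense and intergenic ones included (SD, n = 2). At least 1 read was counted in both libraries for 12300 annotated genes, and at least 5 reads in each library for 8895 genes and 11439 transcript models, of which 8377 were annotated.

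The muscle lists were covered almost completely. All 22 sarcomere genes were detected with at least 3 reads in each library, and summed to 76569 ± 2394 CPM (SD, n = 2), led by Myh6, Tpm1, Myl3 (6217 ± 609.5) and Tnnc1 (6027 ± 794). Excitation-contraction coupling and calcium handling summed to 15243 ± 198 CPM over 15 of 16 detected genes, with Pln, the inhibitor of the calcium pump, at 1611 ± 22.7, Casq2, the calcium store protein, at 1500.4 ± 5.73 and Gja1, the gap junction protein, at 1486 ± 196 beside Atp2a2. For Pln, 1194 of 2563 reads in replicate 1 and 1683 of 3191 in replicate 2 were classed as genomic and left out, and with them counted it stood at 2897 and 3326 CPM. Among 15 of 17 detected cardiac transcription factors and coactivators, Esrra had 299.6 ± 26.5 CPM, Nkx2-5 167 ± 6.80, Gata4 144 ± 8.84 and Mef2a 127 ± 37.5. All 15 splicing regulators were detected, led by Hnrnpu (349.8 ± 24.5 CPM), Qk (317 ± 38.3), Rbm24 (282 ± 10.5) and Mbnl2 (225 ± 1.13). Few reads fell on Ttn, which encodes titin, with 74 and 82 over all classes of model.

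The nuclear lists of oxidative phosphorylation and of fatty acid oxidation summed to more CPM than the glycolysis list. Nuclear-encoded oxidative phosphorylation genes summed to 70342 ± 535 CPM over 19 of 19 detected genes, with Slc25a4, Atp5b, Atp5a1 (8020.2 ± 167) and Uqcrc1 (6399 ± 33.5) highest. Fatty acid uptake and oxidation summed to 32723 ± 601 CPM over 19 of 19, with Fabp3, a fatty acid binding protein, at 7814 ± 1027, Hadhb at 4733 ± 108, Acadvl at 3361 ± 174 and Lpl, a lipase, at 2874 ± 511. Glycolysis summed to 21883 ± 215 CPM over 17 of 17, with Aldoa at 5253 ± 177, Eno3 at 3997 ± 17.2, Ldha at 2978 ± 102 and Pkm at 2617 ± 73.1. Gapdh, which has many near-identical pseudogene copies, had 12 reads in each library, so its level and its part in the glycolysis sum are uncertain. Mitochondrially encoded proteins summed to 2622 ± 114 CPM over 10 of 13, led by mt-Co1 (1214 ± 44.3), mt-Cytb (635 ± 44.0), mt-Nd5 (174 ± 1.51) and mt-Nd2 (162 ± 3.10). All mitochondrial genes together took 0.250% and 0.267% of reads other than spike-ins in replicates 1 and 2. The filters applied to the reads are not given, so this level is uncertain and cannot be set against the nuclear lists.

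Markers of the other cells of the heart ranged from abundant globin and collagen genes to conduction markers near the floor. Fibroblast markers summed to 10945 ± 700.2 CPM (11 of 11 detected), led by the collagen gene Col3a1 (4791 ± 88.9), Gsn (2719 ± 572), Sparc (1346 ± 26.3) and Col1a1 (801 ± 17.5). Erythroid markers summed to 15438 ± 1626 CPM (5 of 7), almost all from the globin genes Hba-a1 (7903 ± 747), Hbb-bs (4097 ± 385), Hba-a2 (2186 ± 257) and Hbb-bt (715 ± 65.0), which are near-identical in pairs, so that the level of each copy is uncertain. Endothelial markers summed to 1333 ± 84.2 CPM (11 of 11; Cav1, Fabp4, Egfl7 and Tie1 highest) and smooth muscle and pericyte markers to 1097 ± 93.6 (10 of 10; Rgs5, Acta2, Kcnj8 and Pdgfrb highest). Macrophage and leukocyte markers summed to 341 ± 51.8 CPM (9 of 11; Lyz2, Cd74, C1qa and C1qc highest), adipocyte markers to 219.9 ± 32.4 (6 of 7; Ucp1, Cfd, Cidec and Adipoq highest) and epicardial markers to 148 ± 7.01 (7 of 7; Upk3b, Msln, Wt1 and Upk1b highest). Atrial markers summed to 3005 ± 259.8 CPM (8 of 9), led by Nppa, a natriuretic peptide (1879 ± 281), Myl7 (420.1 ± 25.5), Myl4 (412 ± 8.07) and Sln (125 ± 9.05). Of the conduction system markers, 1 of 7 was detected, Tbx3 with 3 reads in each library.

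Growth and stress genes were low. Cell cycle genes summed to 258 ± 80.3 CPM (16 of 18 detected; Ccnd2, Rrm2, Mcm2 and Pcna highest), imprinted and growth genes to 633 ± 47.8 (9 of 15; Snrpn, Cdkn1c, Mest and H19 highest) and stress and immediate early genes to 262 ± 39.6 (6 of 11; Ier2, Jun, Junb and Dnajb1 highest). Markers of neighbouring tissues were at or near the floor. None of the 10 skeletal muscle, 6 liver or 8 thymus and lymphocyte markers was detected, and their sums were 3.91 ± 0.580, 0.540 ± 0.763 and 2.24 ± 0.122 CPM. Glial and neuronal markers summed to 17.5 ± 3.32 CPM (2 of 7; Dbh and Sox10). Of the lung markers, 1 of 6 was detected, the club cell gene Scgb1a1, at 129 CPM in replicate 1 and 7.55 in replicate 2.

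In most pairs of genes that encode related forms of a protein, reads favoured 1 gene strongly, and its share was at least 90% in both libraries in 8 of 16 pairs. Myh6 took 99.97% ± 0.0215 of the reads of Myh6 and Myh7 (SD, n = 2), with 5 and 14 reads on Myh7, the beta heavy chain. Tnni3, the cardiac troponin I, took 93.3% ± 3.50 against the slow skeletal form Tnni1, and Actc1, cardiac actin, 89.9% ± 1.12 against skeletal actin Acta1. Of the 273 and 337 Tnni3 reads, 195 and 199 were on forms with a new splice site and 23 and 43 on annotated ones. The Tnni3 count thus rests mostly on unannotated forms. The ventricular light chains Myl3 and Myl2 took 93.8% ± 0.688 and 82.6% ± 1.41 against the atrial Myl4 and Myl7. In metabolism, Ckm took 97.7% ± 0.250 against Ckb, Cpt1b 96.0% ± 0.0101 against Cpt1a, Slc2a4 94.6% ± 3.67 against Slc2a1, Eno3 92.2% ± 0.278 against Eno1 and Pgam2 81.8% ± 3.44 against Pgam1. Nppa took 99.1% ± 0.669 against Nppb. Cox6a2 took 84.9% ± 2.51 against Cox6a1 and Cox8b 57.6% ± 4.25 against Cox8a. In 3 pairs the other form led: Cox7a1 had 34.7% ± 0.170 against Cox7a2, Hk2 36.2% ± 0.709 against Hk1, and Ldhb 46.5% ± 1.86 against Ldha. Each of the 16 shares differed from 50% in both libraries in a two-sided exact binomial test after Benjamini-Hochberg adjustment over pairs and libraries, the highest adjusted p being 0.0124 for Cox8b in replicate 1.

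**Figure D1:**
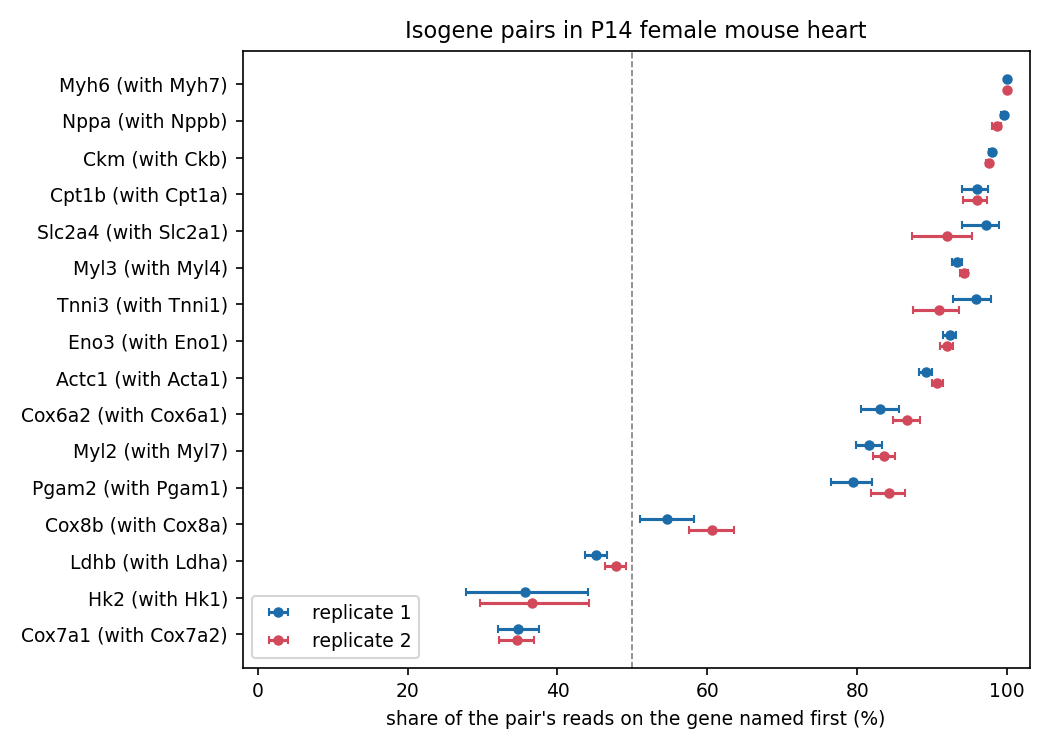
The share of a pair's reads (percent) on the gene named first is shown for 16 pairs in replicate 1 (blue) and replicate 2 (red), with exact 95% Clopper-Pearson intervals as bars and a dashed line at 50%. Myh6 lies at 99.97% on average, and Cox7a1 is lowest at 34.7%.

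Genes with known alternative splicing in striated muscle ranged from a single form to an even mixture. Camk2d, a calcium-dependent kinase, was among the most divided: its leading form, an unannotated combination of known introns with 20 exons, held 27.9% ± 2.35 of usable reads (SD, n = 2), and the annotated Camk2d-202 held 22.0% ± 4.31. Lmna was split between Lmna-203 (56.7% ± 0.660) and Lmna-201 (42.0% ± 0.210), and Fbln2 between Fbln2-202 (59.3% ± 3.55) and Fbln2-201 (40.4% ± 4.00). Vegfa had 44.4% ± 8.43 on Vegfa-207 and 42.8% ± 5.74 on Vegfa-202. Atp2a2 had 88.5% ± 0.490 on Atp2a2-202, and Ldb3, a Z-disc protein, 87.1% ± 1.29 on the short Ldb3-203. Leading shares were 24.3% ± 0.294 for Mff, 33.5% ± 9.25 for Tmpo, 39.4% ± 13.5 for Mef2a, 43.9% ± 1.85 for Dnm1l, 45.7% ± 4.29 for Opa1, 58.5% ± 2.94 for Myl6, 61.5% ± 5.57 for Trdn, 72.4% ± 2.32 for Asph, 79.8% ± 2.03 for Pdlim5 and 81.9% ± 2.03 for Mbnl2. Tnnt2, cardiac troponin T, had 14 and 17 usable reads, all on an unannotated form with 13 exons, while 124 and 133 further reads were incomplete. Ttn had no usable read. For Ldb3, 153 of 413 and 168 of 384 reads were incomplete and likewise left out. With incomplete models counted, 25 isoform results moved beyond their spread and 8 stayed. With annotated models alone, 19 moved and 12 stayed. The shares therefore describe the usable reads and depend on which models are counted. Of 54 listed genes, 32 had at least 20 usable reads in each library, and in 21 of these the leading form held under 90%. The leading form was unannotated in 10. Its share differed between the libraries in 1 gene (two-sided Fisher's exact test with Benjamini-Hochberg adjustment). Before adjustment, 4 genes had p under 0.05.

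Single exons of 24 genes were included in part of the transcripts, and the libraries differed in 1 of 43 such exons, with a median difference of 3.77 percentage points. Of these exons, which had a mean inclusion of 5 to 95%, 35 were in coding sequence and 33 had a length that is a multiple of 3. In Vegfa, a 72-base coding exon (chromosome 17, 46022277 to 46022348) was included in 50.2% ± 7.20 of spanning reads (SD, n = 2). Camk2d included a 42-base exon (chromosome 3, 126808208 to 126808249) in 59.8% ± 1.70 and an 89-base exon that holds coding sequence and UTR (chromosome 3, 126841485 to 126841573) in 51.1% ± 0.388. Mff included exons of 60, 75 and 159 bases in 63.0% ± 1.27, 61.4% ± 5.48 and 35.4% ± 4.20. Opa1 included a 111-base exon in 58.9% ± 0.916 and Dnm1l a 78-base exon in 61.0% ± 3.12. Fbln2 included a 141-base exon in 41.7% ± 4.02, Myl6 a 45-base exon in 36.7% ± 0.0180 and Mef2d a 21-base exon in 64.1% ± 2.21. The exon that differed was a 105-base one of Nebl (chromosome 2, 17417893 to 17417997), included in 85.7% of 35 reads in replicate 1 (95% Clopper-Pearson interval 69.7 to 95.2%) and 11.8% of 34 in replicate 2 (3.30 to 27.5%; Fisher's exact test, adjusted p = 1.37e-08). That call ended when incomplete forms spanning the exon were counted, with 62.3% and 49.4% (adjusted exact p = 1).

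Spliced forms missing from the annotation recurred in both libraries. A set of 1125 unannotated forms had at least 5 reads in each library, in 824 genes; 814 combined known splice sites anew and 311 used a new splice site. The form with the most reads was in Myh6, 4220 and 4703 reads or 16.1% ± 0.532 of the gene (SD, n = 2). It differed from Myh6-201 by a splice acceptor moved by 3 bases, in the intron at chromosome 14, 54942005 to 54942352, and a second Myh6 form with the same change held 4.60% ± 0.00130. Srl had a 3-base acceptor change in 75.6% ± 2.77 of its reads, Idh3b a 289-base one in 80.5% ± 1.89 and Vdac3 a 4-base donor change in 88.6% ± 1.01. In Oaz1 (96.3% ± 0.922) and Oaz2 (91.2% ± 1.46) the form lacked an annotated intron of 4 bases and held no intron of its own. Such forms, 4 of the 1125 with an annotated intron under 30 bases absent, therefore show no new splicing. Idh3g had an unannotated form of 12 exons in 91.3% ± 1.56 and Atp2a2, of 20 exons, in 6.01% ± 0.248. The highest shares were those of Phb2 (97.3% ± 0.795), Oaz1, Mpc1 (96.0% ± 0.508), Mrpl33 (95.8% ± 2.76) and Gbe1 (94.1% ± 0.719). The Gbe1 form had an intron at chromosome 16, 70401850 to 70433544, in place of 70401854 to 70433548. That intron is in another annotated form of Gbe1, so the form joins annotated introns anew. Whether this arose in alignment was not checked, as no genome sequence was used. Of the 1125 forms, 173 differed from an annotated one by a splice site moved by 10 bases or fewer, 97 of them by 3 bases.

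Annotated transcripts took 75.8% ± 0.276 of reads other than spike-ins (SD, n = 2). Incomplete forms took 8.62% ± 0.0498, and 78.7% ± 0.345 of their reads lacked the 5' part only. New combinations took 5.39% ± 0.127, new splice sites 3.32% ± 0.103, antisense loci 3.25% ± 0.288, genomic forms 3.21% ± 0.286 and intergenic loci 0.414% ± 0.00668. By annotated length, 17.1% ± 1.18 of reads on annotated transcripts fell on those under 1 kb, 33.8% ± 0.0577 on 1 to 2 kb, 24.7% ± 0.611 on 2 to 3 kb, 18.2% ± 0.568 on 3 to 5 kb and 6.18% ± 0.0549 above 5 kb. Spike-ins took 1.34% ± 0.0308 of all reads, with 45 of 96 seen in replicate 1 and 41 in replicate 2.

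The last comparison asked how far the libraries differed. Scgb1a1, a secretory protein of lung club cells, was lower in replicate 2, with 111 and 7 reads (log2 ratio -3.93, 95% interval -5.45 to -3.01, adjusted exact p = 6.83e-24). Cebpb, a transcription factor, was lower with 505 and 185 reads (log2 ratio -1.55, 95% interval -1.81 to -1.31, adjusted exact p = 2.00e-37), as were Errfi1, an inhibitor of EGF receptor signalling (156 and 54 reads; log2 ratio -1.62) and Timp4, a metalloproteinase inhibitor (66 and 13 reads; -2.37). Sult1a1, a sulfotransferase, Arrdc2, Hp (haptoglobin) and Kcna5, a potassium channel, were lower with log2 ratios from -1.57 to -1.55. Sox4, a transcription factor, was higher in replicate 2 with 44 and 138 reads (log2 ratio 1.52, 95% interval 1.04 to 2.06, adjusted exact p = 2.00e-08), as were Nr1d1, a clock repressor (15 and 47 reads; 1.48), and Ucp3, a mitochondrial carrier (28 and 80 reads; 1.38). Hyou1, an endoplasmic reticulum chaperone, Rrm2, a subunit of ribonucleotide reductase, Slc35b1 and Angptl4, an inhibitor of lipoprotein lipase, were higher with log2 ratios from 1.22 to 1.40. The call of Rrm2 (adjusted exact p = 0.0498) ended with TMM totals, with no minimum of reads, with annotated models alone and with the length trend subtracted, with log2 ratios between 1.29 and 1.36 there. That of Slc35b1 ended with no minimum (1.23) and with the length trend subtracted (1.20), and those of Hyou1 (1.10) and Nr1d1 (1.56) with annotated models alone. With an assumed coefficient of variation of 0.1, the calls of these 4 genes and of Ucp3, Angptl4, Klf6, Arrdc2, Hp and Kcna5 ended.

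For 5 further genes the size of the ratio or the call changed when all reads overlapping the gene on its strand were counted. The p-values by position were adjusted over the genes counted this way alone, not over all tested genes. Most of these genes had been picked for their large ratios. The pseudogene Vcp-rs had 12 and 176 reads as the files assign them and 182 and 186 by position (log2 ratio -0.09, adjusted exact p = 0.631), and shares sequence with Vcp. Klf9, a transcription factor, had 284 and 26 reads and by position 286 and 171, which moved its log2 ratio from -3.51 to -0.86, and the ratio changed sign when annotated models alone were counted. Cavin1 had 30 and 88 reads and by position 69 and 91 (adjusted exact p = 0.259), which ended its call. Ptpa had 16 and 62 reads and by position 29 and 62 (log2 ratio 0.96, adjusted exact p = 0.0026). Whether its call by position would hold with adjustment over all tested genes was not tested. The calls of Ptpa and Cavin1 ended with annotated models alone (log2 ratios 0.93 and 0.42) and with genomic models counted (0.96 and 0.28). Klf6, a transcription factor, had 44 and 15 reads and by position 66 and 29 (log2 ratios -1.60 and -1.28). The ratio of Slc25a4 moved in the same way, from -0.27 to -0.05, and that of Mpc1-ps from 1.02 to -0.00; both were picked after their values were seen.

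In all, 162 of 9433 tested genes differed in the two-sided exact binomial test with Benjamini-Hochberg adjustment, 74 higher and 88 lower in replicate 2 (45.7% higher). The split was 42 and 87 (32.6% higher) once the trend with transcript length was subtracted and 95 and 83 (53.4% higher) with DESeq2 size factors, and the count dropped to 21 if a coefficient of variation of 0.1 between animals was assumed. The chi-square of the table of counts was 16870 on 9432 degrees of freedom, so the deposited counts differed by more than counting error; separate preparation and annotation of the libraries can add to this, and it does not show that the animals differed. Across genes, which are not independent replicates, log2 CPM correlated with Pearson's r = 0.950 and Spearman's rho = 0.943.

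Among the lists, oxidative phosphorylation genes lay higher in replicate 2, with a median log2 ratio of 0.17 at percentile 99.6 of matched random lists. Of its 19 genes, 9 were higher and 1, Slc25a4, lower over all genes tested, and 10 and 1 adjusted over the list alone. Cox6a2 was at 0.64, Cox8b at 0.52 and Ndufa4 at 0.32. The ratio of Slc25a4 was -0.27, and -0.05 with reads by position. The median of the list was -0.0015 after the length trend was subtracted. The median of the cell cycle list was 0.90 (percentile 100, 9 of 11 members above 0). It was 0.61 (percentile 99.9, 12 of 17 members above 0) with a mean of at least 3 reads, and 0.74 with a pseudocount of 5 CPM. Rrm2 alone passed the test, over all genes, where its call is lost in the settings above, and adjusted over the list alone. Erythroid markers lay lower, at -0.19 (percentile 1.40), with 4 of 5 lower over all genes and 5 adjusted over the list alone, among them Alas2 at -0.68; with the length trend subtracted the median was -0.43 (percentile 0.01). Macrophage and leukocyte markers had a median of -0.35 (percentile 1.85) with no member passing either test. In the sarcomere list, Tpm1, Myl3, Tnnc1, Actc1 and Myl2 were higher over all genes, and 7 higher and 1 lower adjusted over the list alone (median 0.10, percentile 93.6). With the length trend subtracted the sarcomere median was -0.0019 (percentile 48.4), but this check is void, since 16 of 21 members, fewer than 80%, had a length. Elsewhere, Gja1 and Fabp3 were higher, Lpl, Nppa and Gsn lower, Ucp1 higher and Scgb1a1 lower over all genes tested. Adjusted over the list alone, the counts higher and lower were 2 and 0 for calcium handling, 3 and 2 for fatty acids, 1 and 1 for glycolysis, 1 and 1 for transcription factors, 0 and 1 for smooth muscle, atrial, fibroblast and lung markers, 1 and 0 for adipocyte markers, and 0 for every other list.

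**Figure D2:**
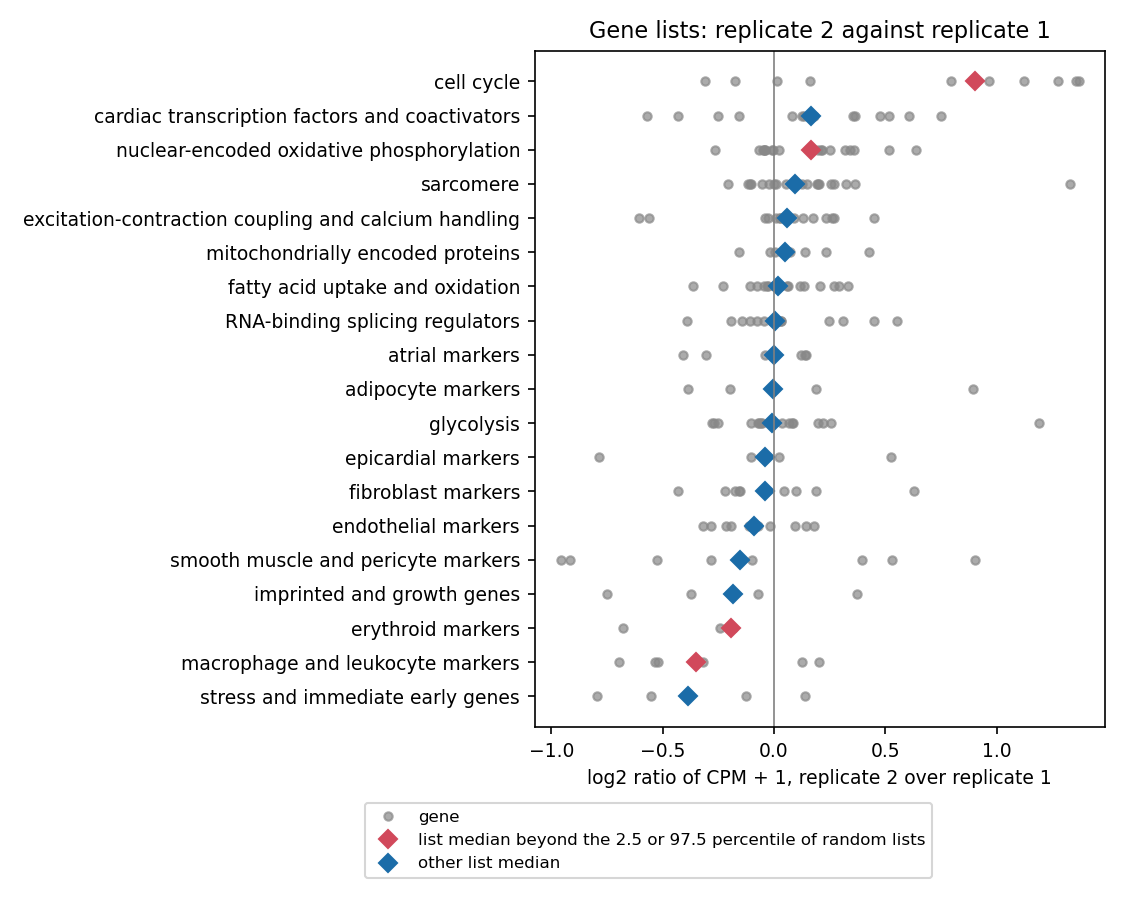
The log2 ratio of CPM + 1, replicate 2 over replicate 1, is shown for the members (grey) and the median (diamond) of 19 lists, red where the median lies outside the central 95% of matched random lists. The cell cycle median is highest of the 19, at 0.90, and that of stress and immediate early genes lowest, at -0.39 (percentile 2.90).

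**Figure D3:**
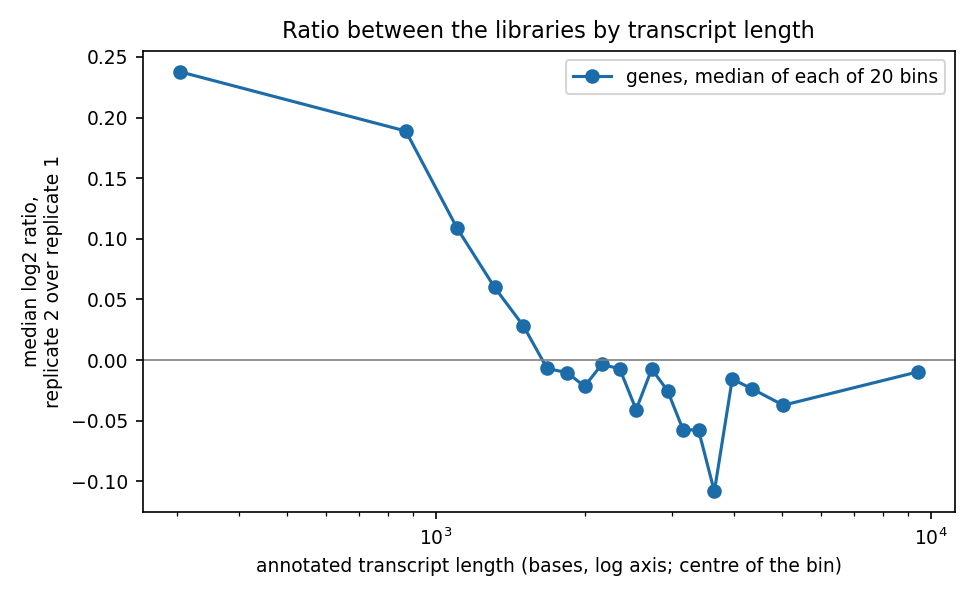
The median log2 ratio, replicate 2 over replicate 1, is shown for 20 bins of genes by annotated transcript length (bases, log axis), each with at least 241 genes. It is 0.24 in the shortest bin and -0.01 in the longest.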

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

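The spike-in tests of length and of strand, the splits of the cell cycle reads that include length, and the loci singled out here, were chosen only after the result was seen. Reads outside annotated genes and spliced forms were singled out for lying above the 3 reads that a count of 0 allows, with no control sample to compare. That bound is for 1 feature, while the totals of these classes are sums over many models. Passing it was thus fixed in advance for the totals and shows nothing about them. Antisense loci held 30591 reads in replicate 1 and 29258 in replicate 2, intergenic loci 3621 and 4017, and genomic forms 26647 and 32774. An antisense locus opposite Tnnt2 (chromosome 1, 135849741 to 135852260, minus strand) held 247 and 252 reads. The intergenic locus with the most reads (chromosome 11, 31545795 to 31549650, plus strand, 2 exons, 115531 bases from its nearest gene, Bod1) held 262 and 244.

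Antisense reads lay at similar depth in both libraries opposite Klhl31 (562 and 516 reads) and Nfia (479 and 481), while a locus on Mpc1-ps, opposite Zfp839 (chromosome 12, 110858070 to 110858565), had 174 and 0 only as classed, since Mpc1-ps had 342 and 370 reads by position, and 96.9% of antisense reads were on forms with 1 exon. Reads given the wrong strand were argued against as the main source by the spike-ins, of whose reads 0.896% lay on the antisense strand, against 3.25% of all reads on antisense loci. Run-on of a gene on the same strand past its annotated end was argued against as the main source, since 13.4% of antisense reads were on forms starting within 5 kb downstream of such a gene. Priming inside genomic DNA or unspliced RNA stays open, since it needs the genome sequence, which was not used here. No biological explanation was tested, as the design holds 1 group.

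The oxidative phosphorylation genes, Cox6a2 and Cox8b among them, had a median log2 ratio of 0.17 between the libraries. After the ratio of genes of like length was subtracted, the median was -0.0015 (95% interval over resampled members -0.03 to 0.09), which is consistent with a length bias between the libraries as the source. The spike-ins, which carry no biology of the hearts, shifted the same way: reads on those under 800 bases over reads on longer ones were higher in replicate 2 by a log2 ratio of 0.15 (exact 95% interval 0.07 to 0.23), from 2815 and 9286 reads to 3202 and 9518. That interval covers counting error and not the spread among spike-ins. The 4 spike-ins with the most reads held 86.3% and 84.9% of spike-in reads in replicates 1 and 2, and of these only ERCC-00074 was under 800 bases. A trend arising in library preparation may account for the median of this list, though few spike-ins carry the check. It leaves part of the ratios of Cox6a2 (0.64) and Cox8b (0.52) unaccounted for, since the highest median of any length bin was 0.24. No biological explanation was tested.

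The cell cycle genes had a median log2 ratio of 0.90, with Ccnd2 at 21 and 40 reads, Mcm2 at 14 and 34 and Rrm2 at 15 and 43, although Pcna had 21 and 20. Counting noise was argued against for the 11 members with a mean of at least 10 reads. Of 10000 random splits of their reads by the library totals, 0 gave a median as large, the highest being 0.74. Length bias was argued against as the whole source: with the ratio of genes of like length subtracted the median was 0.94, although its interval over resampled members was wide (-0.01 to 1.28). When each member's reads were split by that ratio as well as the totals, 0 of 10000 splits gave a median as large, the highest being 0.69. No splits were run for the 17 members with a mean of at least 3 reads, whose median log2 ratio was 0.61 with 5 members lower in replicate 2. A difference in the animals or the tissue taken stays open and untested.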

How the results depend on the processing

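Values with genomic models counted in the gene results, the length trend subtracted and reads by position were chosen only after the result was seen. Of the alternative values of results that answer a comparison, 63 stayed within their spread, or within 1.5 times for a count, and 18 moved; of those of single genes, lists, exons and forms, 646 stayed, 98 moved, 39 lost their call, 1 gained it and 3 reversed. The counts of detected genes and models, of detected list members and of called gene pairs, the share of reads under 1 kb and the spike-in share stayed under every alternative run for them. Among reads by novelty class, the share on annotated models was 78.3% with genomic models left out, whose construction removes other reads. The count of reproducible unannotated transcripts was 2069 with a minimum of 3 reads, 534 with 10 reads, 1815 to 1872 with 1 library required, and 0 when matched by the identifiers in the files, which differ by library. With a coefficient of variation of 0.1, 21 genes differed (7 higher, 14 lower; 10 of the 20 named genes), and with 0.2, 9 differed (3 higher, 6 lower; 4 named), since the test then allows for more spread. The genes higher in replicate 2 numbered 49 with annotated models alone and 42 with the length trend subtracted. Incomplete models counted gave 37 genes with a leading share under 90%, and annotated models alone gave 14 exons in place of 43, since fewer forms were counted; for the 49 and the 37 the cause was not tested. Klf9 reversed to a log2 ratio of 0.058 with annotated models alone and Vcp-rs to -0.085 with reads by position, both through the class or gene given to the same reads. The oxidative phosphorylation list moved from percentile 99.6 to 48.0 with the length trend subtracted. The stress and immediate early genes moved from percentile 2.90 to 1.09 with genomic models counted; the cause was not tested. Depth limits all of this: 1 read is 1.17 or 1.08 CPM, and 32 of the 54 isoform genes had enough usable reads for a test. In the simulation a 2-fold change was recovered for 61% of genes, all with at least 50 reads in all. Genes with fewer reads were not tried there. No paired analysis was possible because there is 1 group.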

Other observations

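No test in this part was chosen only after its result was seen, but the pattern it starts from was found in these data, and the tests were first listed under the cell cycle genes. Listed glucocorticoid-responsive genes were lower in replicate 2. Tsc22d3, a classical target of the glucocorticoid receptor, had 399 and 204 reads in replicates 1 and 2, Dusp1, a phosphatase, 191 and 147, Sesn1 209 and 149, Sgk1, a kinase, 98 and 70, Mt1, a metallothionein, 82 and 45, Cebpd 57 and 39, and Cdkn1a, a cell cycle inhibitor, 29 and 6. Of 15 listed genes, 14 had any read, and all 14 had a lower CPM in replicate 2. The list is a choice of such genes, and responsive genes outside it were not examined as a set. Angptl4 (25 and 64 reads) and Pdk4 (437 and 544, not past the threshold), which it does not hold, were higher in replicate 2. For the 7 with a mean of at least 10 reads the median log2 ratio was -0.65, at percentile 0 of 10000 matched random lists. Macrophage and leukocyte markers (median -0.35, percentile 1.85) and erythroid markers (-0.19, percentile 1.40) lay lower too, below percentile 2.5. Stress and immediate early genes had a median of -0.39 but stayed inside that bound (percentile 2.90, with Jun at -0.79 and Junb at -0.55). No member of the stress list or of the macrophage and leukocyte list passed the test, over all genes or over its list alone. Lung markers summed to 139.8 CPM in replicate 1 and 8.63 in replicate 2, with Scgb1a1 at 111 and 7 reads and, picked after their values were seen, Sftpa1 at 5 and 0 and Sftpd at 2 and 0.

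The list was written after Klf9, Errfi1 and Cebpb, known to respond to glucocorticoids, had been seen lower in replicate 2, and it leaves these 3 genes out. The hypothesis tested was that glucocorticoid signalling was higher in the heart tissue of replicate 1, which the labels do not clearly tie to 1 animal, and the length-corrected median of -0.59 (95% interval over resampled members -1.20 to -0.54) is consistent with it. Several of these genes also respond to stress, time of day and handling of tissue, so the source of such a difference, the tissue taken included, stays open, and part of the drop of Klf9 itself came from the class given to its reads, with a log2 ratio of -0.86 by position. A different clock phase of the tissue in the libraries, prompted by Nr1d1, was left undecided. Genes of the Nr1d1 phase minus those of the opposite phase gave 0.40 (95% interval over resampled members -1.10 to 1.36). Dbp had 31 and 56 reads and Nr1d2 18 and 35, but Per2 had 17 and 7. These values cannot be told apart from chance with 7 genes in the 2 lists.

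The same structure was not always given the same class in both libraries. Of 3062 unannotated structures with at least 5 reads in each library, 187 (6.11%) had different class names, and 48 of these were incomplete in one library and a new combination or new splice site in the other. They held 3184 reads in replicate 1 and 3253 in replicate 2.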
